A study of Homo sapiens with 5 samples.

How the data were processed

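Gene expression was measured in cells differentiated from H1, an established human embryonic stem cell line. Per the labels' protocols, mesoderm was induced with CHIR99021, an inhibitor of GSK3 that activates canonical WNT signaling, on a matrigel coating, and the medium was replaced each day. From day 2 to day 5 the cells received IWP2, LY294002, insulin, or IWP2 together with LY294002, and control cells stayed in the basal differentiation medium. IWP2 blocks Porcupine and thereby WNT secretion, LY294002 inhibits phosphoinositide 3-kinase (PI3K), and insulin activates PI3K through its receptor. Cells were harvested on day 10, total RNA was isolated with a Qiagen column kit, and biotin-labelled cRNA was made for an Illumina expression BeadChip, per the labels' protocols. Each of the 5 conditions has 1 array, taken to its group by the treatment label.

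The deposited scanner-level table gives, per the file headers, an intensity for each of 47299 probes on each array and a detection p-value beside it. The intensities were not normalized and still held the background, as the lowest value of each array lay between 81.3 and 85.9. The detection p-values moved in steps of 1 in 770, as a rank among 770 negative control probes gives. A separate deposited value table holds log2 values. How the authors made it is not given in the sources used here. From the values, its columns have nearly 1 distribution, with medians from 5.013 (IWP2 and insulin) to 5.017 (LY294002), and nearly each array's order of intensities (Spearman correlation over 0.9999). It was therefore taken as quantile-normalized, on a log2 scale that the comparison with the intensities bears out. The exact background reduction behind it stays unknown.

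The intensities were background-corrected with the normexp model, taking the mean and variance of the negative controls from the detection p-values, then quantile-normalized over the 5 arrays and moved to the log2 scale with an offset of 16 (function neqc of limma 3.58.1 in R 4.3.3). Later steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. A probe was called detected where its detection p-value lay under 0.01. Between 13173 (LY294002) and 14723 (IWP2) probes were detected per array. Median intensities ran from 106.9 (LY294002) to 118.2 (insulin), and 95th percentiles from 469.7 (LY294002) to 815.3 (insulin), so the LY294002 array was the dimmest. The number of arrays limits the precision, and no replicate check was possible.

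Probes were named from the platform annotation. Of the probes, 30106 had 1 gene symbol, 8 had several and were not named, and 17185 had none in that table. The named probes stood for 20041 genes, of which 10976 were detected on at least 1 array and 7110 on all 5. For the 6690 genes with several probes, the probe with the highest mean log2 intensity over the 5 arrays was used. TNNT2 was not analysed here.

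With 1 array per group there is no spread between replicates, so no p-value, standard error or standard deviation between replicates was computed and no difference was tested. Each comparison is a difference of normalized log2 intensities between 2 arrays. A gene counted as at least 2-fold higher or lower where it was detected on both arrays and the log2 difference was 1 or more in size. A gene detected on only 1 of the 2 arrays has only a bound: the bright value was set against the higher of the dim array's lowest detected signal and the gene's own dim value, and is given as "at least N-fold". All comparisons with the control use the same control array, so an error of that array enters each of them. Correlations across genes were therefore computed only between differences that share no array.

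The 30 gene lists, the 2-fold threshold, the comparisons and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison with the control, the 10 genes with the largest difference in each direction among genes detected on both arrays, the 5 largest bounds in each direction, up to 4 members of each list with the largest difference, and IGF1, IGF2, IGF1R, INSR, TNNT2, NKX2-5 and AXIN2. For the other comparisons and the 2 by 2 difference it took 5 genes in each direction. It also asked for any named gene with another detected probe moving the other way by at least 0.58, which no gene named in a comparison with the control had. Placeholder symbols and Y-linked genes were counted but not named. For each list, the median log2 difference of the members detected on at least 1 array is given with its percentile among 10000 random lists of the same size matched on mean intensity in 10 bins. The percentile describes these arrays and is not a p-value.

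The code was tested on simulated arrays with an assumed noise SD of 0.1 on the log2 scale for the IWP2 and control pair. Of 36 genes made 4-fold higher and 43 genes made 4-fold lower, 100% were counted past 2-fold, with median log2 differences of 1.92 and -1.83. None (0%) of 36 genes made 1.5-fold higher and 0% of 13134 unmoved genes were counted. With the simulated LY294002 array dimmed and compared with the control, 0% of 12227 unmoved genes were counted. The noise was set well under the 2-fold threshold, so the counts of 0% check the code and give no error rate. The measured log2 differences of 2 probes of the same gene gave a robust SD per probe of 0.385 to 0.465 over the 4 comparisons with the control. This is the spread between the 2 probes divided by the square root of 2, so that spread itself is larger. Of 200 random lists, 6% fell outside the 2.5 to 97.5 percentile range.

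The alternatives were no background correction, a saddle-point normexp fit with an offset of 50, the same negative-control correction with an offset of 50, 75th percentile scaling, cyclic loess, the deposited log2 values, a detection p-value limit of 0.05, no detection filter, the mean over a gene's detected probes, list means, and fold thresholds of 1.5 and 3. Normalization without the LY294002 array was added after the data were seen, as were a correlation of the insulin difference with the IWP2 difference on LY294002 and lists of adult hepatocyte and imprinted genes. No genomic coordinates are given, because no genome build is named in the sources used here.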

Results

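The data are 5 expression arrays of H1 human embryonic stem cells at day 10 of CHIR99021-induced mesoderm differentiation. The control, IWP2, LY294002, insulin, and IWP2 with LY294002 each had 1 array. No condition has replicates, so differences between arrays could not be set against replicate error and no p-value can be given. The design asks how blocking WNT secretion, blocking PI3K, blocking both, or adding insulin between day 2 and day 5 bears on the cell types present at day 10, and the series title names endogenous IGF signaling as its subject. On the log2 scale over the 7110 genes detected on all 5 arrays, the control and insulin arrays were the most alike (Pearson r = 0.962) and the insulin and double-inhibitor arrays the least (r = 0.790).

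The control array carried strong signals of liver genes. AFP, the fetal serum protein of yolk sac and liver, read 14.18 on the log2 scale in the control, and the median of the 21 detected endoderm and liver genes was 11.68. The cardiomyocyte list holds genes of contractile and calcium-handling proteins and others such as CKM, CKMT2, MB, NPPA and NPPB. Of its 35 genes detected on any array, 23 were detected on the control array. Their median there was 5.95, but the brightest read near 12: MYL4 12.14, MYH6 11.98, ACTC1 11.95, SLN 11.90 and MYL7 11.84. The control array thus carried strong signals of some cardiomyocyte genes as well. Signals of different probes do not rank transcript abundance. Among the 100 brightest genes of the control array, 7 were endoderm and liver list members. IGF2, a growth factor of the insulin family, was detected on the control array (6.89) and the insulin array (7.83) and not on the 3 inhibitor arrays. The probes used for IGF1 and IGF1R were not detected on any array. That for INSR, the insulin receptor, was detected only on the IWP2 (5.51) and LY294002 (5.89) arrays. Both values lay near the lowest detected signals of those arrays (5.27 and 5.49). A probe without detected signal does not show that a transcript is absent.

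IWP2 compared with control. Cardiac genes were higher and liver, matrix and epicardial genes lower on the IWP2 array. Of the 22 cardiomyocyte genes detected on both arrays, 19 were at least 2-fold higher and 1 lower, and 11 more were detected only with IWP2. The median log2 difference over the 35 list members was 1.97 (percentile 100). CKM (muscle creatine kinase) was higher by 3.36, MB (myoglobin) by 3.14, CKMT2 (mitochondrial creatine kinase) by 3.06 and MYL3 (a ventricular myosin light chain) by 3.04. Among cardiac transcription factors, NKX2-5 was higher by 3.50, IRX4 by 3.29 and SMYD1 by 3.27, and MEF2C was at least 6.36-fold higher. That list had a median of 0.45 (percentile 98.8), with 6 of 16 genes higher and 0 lower. The oxidative phosphorylation and fatty acid oxidation list had a median of 0.86 (percentile 100), with 7 of 22 genes higher and 0 lower, led by PPARGC1A (2.96), a coactivator of mitochondrial genes.

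Of the 19 endoderm and liver genes detected on both arrays, 16 were at least 2-fold lower with IWP2 and 0 higher (list median -1.89, percentile 0). APOC3 had a log2 difference of -3.56, FGA of -2.72, RBP4 of -2.69 and AHSG of -2.62, all genes of secreted liver proteins. Of 21 fibroblast and extracellular matrix genes, 13 were lower and 1 higher (median -1.28, percentile 0). DCN (decorin) had the largest negative difference of all genes detected on both arrays (-4.04), COL6A3 differed by -3.09 and THY1 by -2.38, while FBN2 was higher by 2.39. In the epicardium and mesothelium list, 6 of 7 genes were lower (median -1.21, percentile 0), among them TBX18 (-1.67), BNC1 (-1.58) and WT1 (-1.47). The epithelium list had a median of -0.86 (percentile 0.01), with CLDN3 at -1.81 and CRB3 at -1.72. The endothelium list had a median of -0.67 (percentile 0.1), with TEK at -1.85.

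PITX1, a hindlimb transcription factor, differed by -3.92 and LHX2 by -3.89. HOXB5 differed by -2.79 and HOXB4 by -1.90, within a HOX list median of -0.80 (percentile 0.65). In the list of WNT ligands and antagonists, FRZB (-2.79) and SFRP5 (-2.16), which encode secreted WNT antagonists, were lower, and WNT11 (2.28) and WNT2 (1.93) were higher. The list of canonical WNT target genes had a median of -0.09 (percentile 31.8), and AXIN2, a feedback target of the pathway, differed by -0.74. The remaining genes with the largest positive differences were XPO4 (3.58), ENO3 (3.48), DDIT4L (3.41), FHOD3 (3.38), RBM24 (3.35) and MAP3K20 (3.22). Those with the largest negative differences were TMEM200A (-3.65), MS4A10 (-3.45), GAP43 (-3.40), FKBP11 (-3.35), APOC2 (-3.28) and LRRTM1 (-3.28). LAMA4 was at least 8.80-fold and MARCHF11 at least 7.32-fold higher, and CREB3L3 was at least 11.5-fold and MT1G at least 11.3-fold lower. Over the array, 584 of 8414 genes detected on both arrays were at least 2-fold higher and 648 lower. Without background correction the list medians were 1.19 (cardiomyocyte), -0.62 (epicardium) and -0.26 (endothelium), and without a detection filter -0.14 (epithelium) and -0.20 (HOX).

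LY294002 compared with control. The same groups stood apart, with liver genes further below the control. Of 21 cardiomyocyte genes, 17 were at least 2-fold higher and 1 lower, and 11 more were detected only with LY294002 (list median 1.64, percentile 100). MB was higher by 4.23, CKM by 3.78, PLN (phospholamban, a regulator of the calcium pump) by 3.27 and MYL3 by 3.11. IRX4 was higher by 3.39, NKX2-5 by 3.21 and SMYD1 by 3.01, and IRX5 was at least 11.1-fold higher. The oxidative metabolism list had a median of 0.68 (percentile 99.98).

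Of 15 endoderm and liver genes detected on both arrays, 14 were lower and 0 higher, and 6 more were detected only on the control (list median -3.68, percentile 0). APOC3 differed by -6.66, AHSG by -5.79, FGA by -5.14 and APOA4 by -5.09. GSTA1 (-5.78), FGG (-4.71), FGB (-4.69), GSTA2 (-4.46), APOB (-4.41) and SERPINA1 (-4.29) completed the 10 largest negative differences. Of 20 fibroblast and matrix genes, 14 were lower (median -1.71, percentile 0), led by PDGFRB (-3.14) and COL6A3 (-2.86). The epithelium list had a median of -1.85 (percentile 0), and CDH1, which encodes E-cadherin, was at least 14.4-fold lower. The epicardium list had a median of -1.04 (percentile 0.01) and the endothelium list of -1.12 (percentile 0.01). Of the 16 endothelial members 9 were detected only on the control, and with undetected members at their bounds the median was -0.35.

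The pluripotency list had a median of -1.03 (percentile 0.03), with DPPA4 at -1.97, LIN28A at -1.36, SALL4 at -1.24 and LIN28B at -1.18. FOXO target genes, whose transcription insulin signaling is known to restrain, had a median of -0.73 (percentile 0.21). BCL6 was at least 3.69-fold lower and TRIM63 higher by 1.54. With undetected members at their bounds the FOXO median was -0.26. Such restraint would place the list higher with LY294002 and lower with insulin, and the medians (0.39 with insulin) lay the other way. Treatment ended on day 5 and the cells were harvested on day 10. TRIM63 is also a cardiomyocyte list member and was higher by 2.37 with IWP2. The cholesterol and fatty acid synthesis list had a median of -0.53 (percentile 0.45), with FADS1 at -1.91 and FASN at -1.69. PSAT1, an enzyme of serine synthesis, differed by -2.32 within an amino acid and endoplasmic reticulum stress list median of -0.68 (percentile 0.16). ODAM (3.98), WNT2 (3.58), ENO3 (3.24), GJA3 (3.22) and XPO4 (3.20) completed the largest positive differences. Of 7793 genes, 703 were at least 2-fold higher and 793 lower (19.2%). The LY294002 array was the dimmest, and 1469 genes were detected only on the control against 637 only with LY294002. Without background correction the list medians were 1.05 (cardiomyocyte), -0.53 (epicardium), -0.26 (FOXO targets), -0.27 (IGF and insulin pathway) and -0.26 (amino acid and stress), and without a detection filter -0.43 (endothelium), -0.41 (epithelium), -0.17 (neural crest) and -0.10 (pluripotency).

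Insulin compared with control. The insulin array differed least from the control, with 148 of 8680 genes at least 2-fold higher and 163 lower (3.58%), a balance that turned with the scaling (123 and 202 under 75th percentile scaling, 186 and 146 under cyclic loess). Cardiomyocyte genes were lower: of 18 detected on both arrays, 9 were at least 2-fold lower and 1 higher, and 5 more were detected only on the control (list median -0.51, percentile 0). That median was -0.20 without background correction. SMPX differed by -1.37, NEBL by -1.35, PLN by -1.32, HRC by -1.26 and CKM by -1.21. IRX4 was at least 2.67-fold and NKX2-5 at least 2.06-fold lower, while HOPX, a cardiac homeodomain cofactor, was higher by 2.07. Liver genes stayed close to the control: of the 21 endoderm and liver genes 0 passed 2-fold (median 0.14, percentile 93.2). The fibroblast and matrix list median was 0.00 (percentile 61.5).

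The fetal globin genes HBG2 and HBG1 and the embryonic globin gene HBE1 were detected with insulin and not in the control, and HBG2 was also detected with IWP2 (5.65 on the log2 scale). With insulin HBG2 was at least 4.39-fold and HBG1 at least 3.38-fold higher, and HBE1 at least 1.66-fold higher, within a blood list median of 0.78 over 7 members (percentile 99.98), which was 0.19 without a detection filter. In the IGF and insulin pathway list (median 0.23, percentile 97.6), IGFBP3 was higher by 1.39, IGF2R by 1.30 and IGF2 by 0.94. The glycolysis and hypoxia list had a median of 0.24 (percentile 99.6), the FOXO target list of 0.39 (percentile 99.8) with CITED2 at 1.61, and the cholesterol synthesis list of 0.22 (percentile 99.1) with EBP at 1.24. The remaining largest positive differences were GEMIN4 (2.76), NNAT (2.55), MED16 (2.32), TSPY26P (1.82), SRSF8 (1.82), PECR (1.82), INKA1 (1.81), COMMD7 (1.78) and TLN2 (1.78). Of these, GEMIN4, NNAT, MED16, TSPY26P, SRSF8 and COMMD7 were also higher than the control on each inhibitor array, and PECR, INKA1 and TLN2 were not. GEMIN4 read 5.43 in the control, 8.20 with insulin, and 7.65, 8.12 and 7.65 with IWP2, LY294002 and both inhibitors. CITED2 was also higher than the control on each inhibitor array. CITED2 read 7.33 in the control, 8.94 with insulin and 8.615 with LY294002. The largest negative differences were PNISR (-2.14), RNF150 (-2.01), BLOC1S1 (-1.98), TRIM55 (-1.76), SERTAD4-AS1 (-1.73), ORC3 (-1.71), GABRP (-1.65), FILIP1 (-1.65), GOLIM4 (-1.62) and PCNT (-1.61). Of 67 genes past 2-fold with a second detected probe, the second probe had the same sign in 47 (70.1%) and was itself past 2-fold in 8.

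IWP2 with LY294002 compared with control. The double-inhibitor array differed most from the control. Of 9 endoderm and liver genes still detected on both arrays, 8 were at least 2-fold lower, and 12 more were detected only on the control, 10 of them with a bound past 2-fold (list median -5.29, percentile 0). APOA4 was at least 217-fold, AHSG at least 180-fold and APOC3 at least 110-fold lower. SERPINA1 differed by -6.88, TTR by -6.65, FGA by -6.35, FGB by -6.20, APOA2 by -5.60 and AFP by -5.29. Fibroblast and matrix genes were lower too (median -2.66, percentile 0), with LUM at least 138-fold, COL6A3 at least 36.0-fold and DCN at least 30.7-fold lower and COL1A2 at -4.49. The imprinted growth regulators DLK1 (-6.81) and H19 (-5.96) were among the largest negative differences, with NHERF1 (-5.61) and GSTA2 (-5.53).

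Of 21 cardiomyocyte genes, 17 were higher with both inhibitors and 0 lower, and 11 more were detected only there (median 2.08, percentile 100). CKM was higher by 3.61, MYL3 by 3.25 and MYH7 (slow myosin heavy chain) by 3.15, and SLC8A1, the sodium-calcium exchanger, was at least 8.54-fold higher. SLN (sarcolipin, an atrial regulator of the calcium pump) went the other way and was at least 87.1-fold lower. SMYD1 was higher by 4.02, NKX2-5 by 2.81 and IRX4 by 2.75, though the cardiac transcription factor list as a whole had a median of 0.04 (percentile 54.3). PPARGC1A was higher by 3.67 and FABP3 by 2.29, in an oxidative metabolism list with a median of 0.84 (percentile 100). ODAM (4.22), XPO4 (4.14), KLHL41 (3.86), LMO3 (3.82), FHOD3 (3.65), LRRN3 (3.57) and HSPB3 (3.56) completed the largest positive differences.

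Proliferation genes were lower with both inhibitors: of 30 detected on both arrays, 16 were at least 2-fold lower and 0 higher (median -1.18, percentile 0). CDC20 differed by -2.36, KIF20A by -2.05 and TOP2A by -1.89, and AURKB was at least 4.34-fold lower. That list's median was -0.34 (percentile 0.69) with IWP2, -0.12 (percentile 28.5) with LY294002 and -0.14 (percentile 10.7) with insulin. SLC2A1, the glucose transporter, differed by -3.01 and PHGDH, an enzyme of serine synthesis, by -2.36. In all, 940 of 7858 genes were at least 2-fold higher and 854 lower (22.8%; 867 and 929 under 75th percentile scaling), and 1412 were detected only on the control. Without background correction the list medians were 1.28 (cardiomyocyte), -1.58 (fibroblast and matrix), -0.71 (proliferation), -0.59 (epicardium), -0.25 (endothelium), -0.25 (WNT targets), -0.34 (IGF and insulin pathway), -0.35 (cholesterol synthesis) and -0.55 (amino acid and stress), and without a detection filter -0.36 (epithelium), -0.23 (neural crest), -0.18 (limb and lateral plate), -0.14 (cartilage), -0.16 (HOX) and -0.10 (pluripotency).

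**Figure D1:**
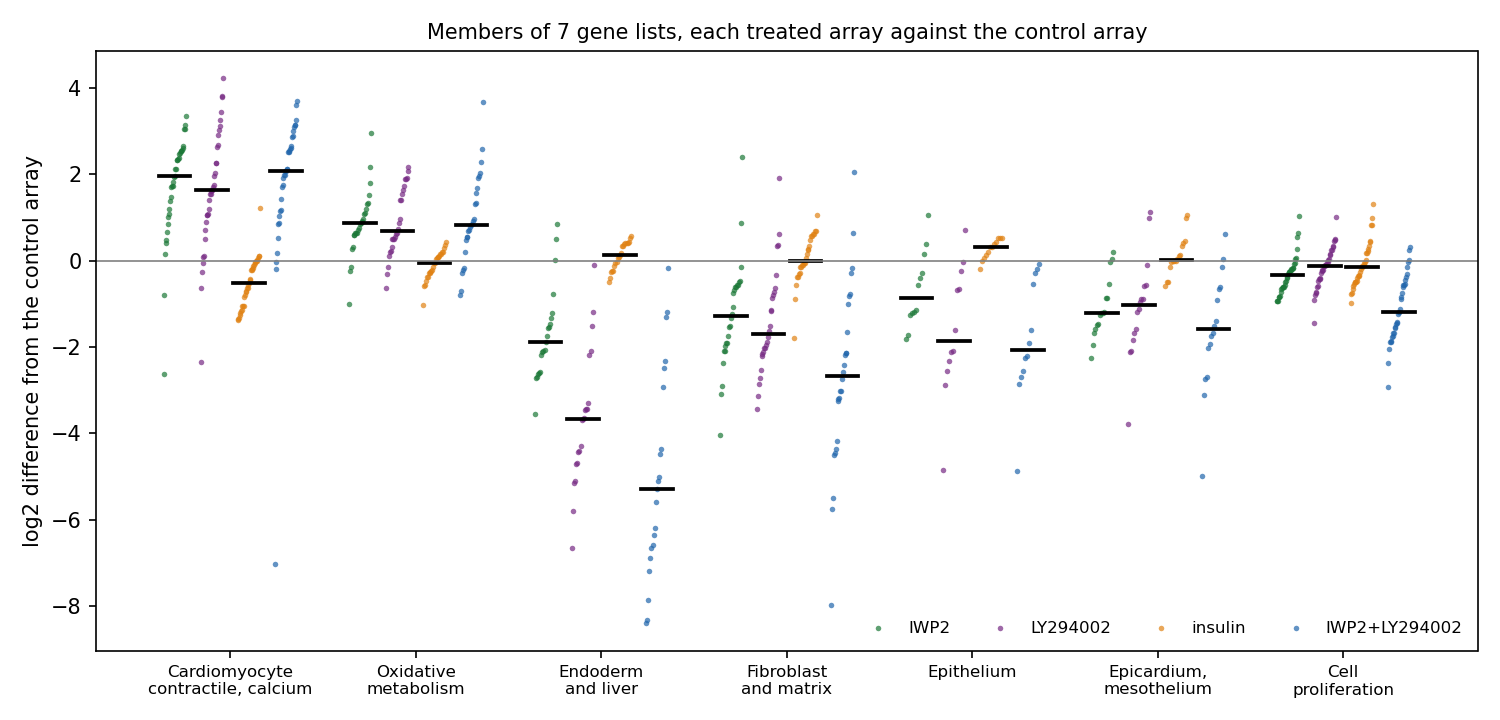
Each point is 1 gene of a list, detected on at least 1 of the 5 arrays, at its log2 difference from the control array on the vertical axis; colours mark the treated array, black bars list medians, and genes near the background are drawn at their measured difference. The cardiomyocyte medians were 1.97, 1.64, -0.51 and 2.08 and the endoderm and liver medians -1.89, -3.68, 0.14 and -5.29 for IWP2, LY294002, insulin and both inhibitors.

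**Figure D2:**
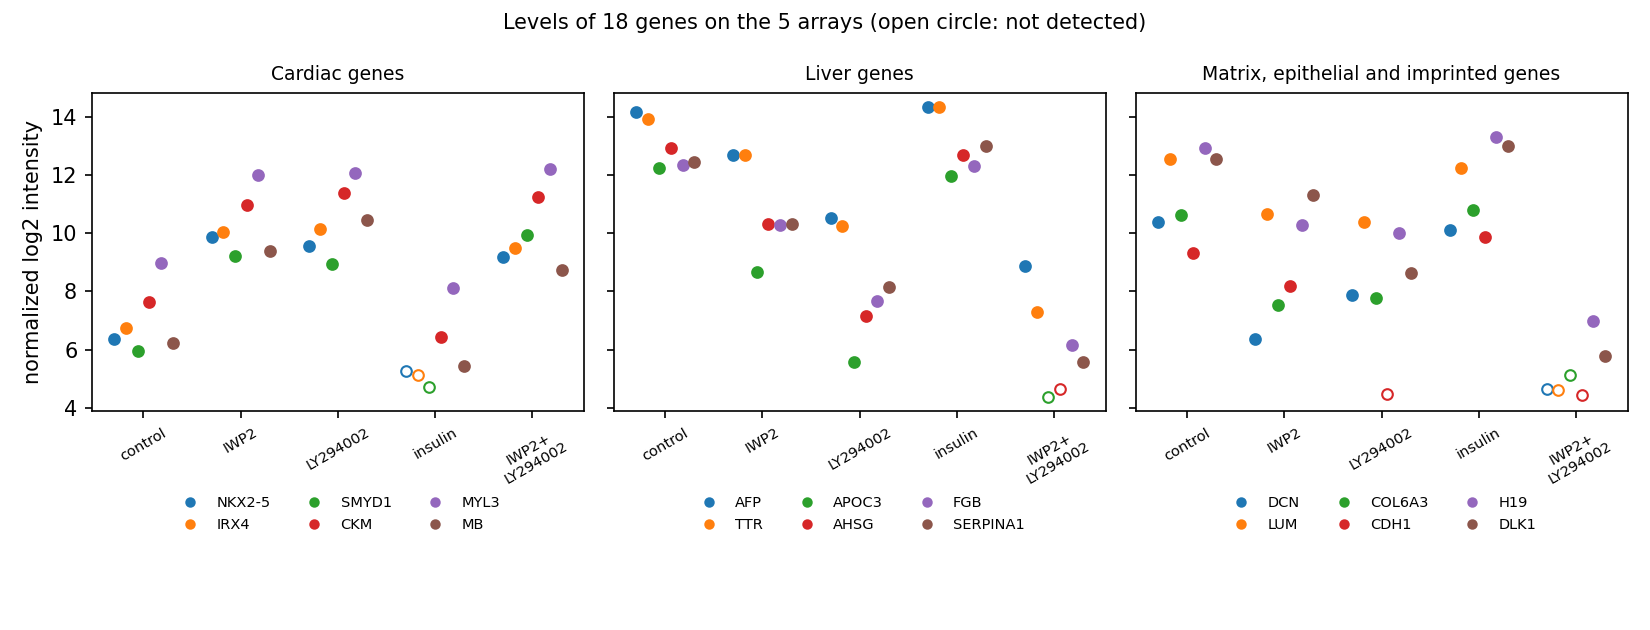
Normalized log2 intensities of 18 genes, chosen after their values were seen, on the 5 arrays (1 array per condition); filled circles were detected and open circles were not. AFP read 14.18 in the control and 8.89 with both inhibitors, and NKX2-5 read 6.37 in the control and 9.87 with IWP2.

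Further list medians against the control follow in the order IWP2, LY294002, insulin and both inhibitors. Epithelium stood at 0.31 with insulin and at -2.07 with both (percentile 0), where all 12 detected members had a negative difference. The epicardium list stood at 0.02 with insulin and at -1.59 with both (percentile 0), where 14 of 16 members had a negative difference. Endothelium stood at 0.28 and -0.79. Smooth muscle gave -0.15, -0.44, -0.09 and -0.25. Neural crest gave -0.33, -1.0, 0.04 and -1.04, and limb and lateral plate mesoderm -0.17, -0.11, -0.15 and -0.90, with MSX1 at -4.79 with both inhibitors. Cartilage gave 0.06, -0.46, 0.04 and -0.77. Pluripotency gave -0.52 with IWP2, -0.04 with insulin and -0.93 with both. The lists of few detected members were blood (0.28, 0.05 and -0.10 for the 3 inhibitor arrays), presomitic and somitic mesoderm (0.04, -0.12, 0.27, -0.32), neural (0.11, -0.11, 0.05, 0.27), intermediate mesoderm and kidney (-0.50, -0.15, -0.15, -0.42), and primitive streak (0.35, 0.16, -0.06, 0.99). Skeletal muscle gave 0.10 with IWP2 and 0.13 with both, and its LY294002 and insulin medians were within 0.04 of 0. The primitive streak value of 0.99 rests on 5 genes near the background and turned to -0.15 at a detection limit of 0.05.

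Several list medians rest on members not detected on 1 of the arrays, and the following moved by over 1.5 times or turned sign with such members at their bounds. With both inhibitors the bounded medians were -1.05 for epicardium, -0.36 for endothelium, -0.57 for neural crest, -0.29 for limb and lateral plate mesoderm, -0.10 for cartilage, -0.19 for presomitic mesoderm, -0.26 for kidney and 0.21 for skeletal muscle. They were also -0.18 for canonical WNT targets, -0.42 for HOX genes and -0.56 for the amino acid and stress list. With LY294002, besides endothelium and FOXO targets, they were -0.37 for neural crest, -0.06 for cartilage, -0.07 for presomitic mesoderm, 0.00 for limb and lateral plate mesoderm, -0.08 for canonical WNT targets, -0.25 for the IGF and insulin pathway and -0.41 for the amino acid and stress list. The signs turned there for kidney (0.11) and skeletal muscle (0.23). With IWP2 they were -0.43 for endothelium, -0.16 for neural crest, -0.14 for the IGF and insulin pathway, 0.03 for skeletal muscle and 0.07 for the neural list. With insulin they were -0.34 for cardiomyocyte genes and -0.10 for kidney. The IGF and insulin pathway median with both inhibitors moved less, to -0.41, as did the cardiomyocyte medians with the inhibitors, to 1.75, 1.40 and 1.98.

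Among the signaling lists, BMP and TGF-beta genes gave 0.47, -0.21, 0.04 and 0.29, with BMP7 at 2.65 with LY294002 and TGFB2 at 3.28 with both inhibitors, where TGFBI was at least 41.3-fold lower. WNT ligands and antagonists gave 0.22, 0.32, 0.14 and 0.15. Canonical WNT targets gave -0.12 with LY294002, -0.01 with insulin and -0.59 (percentile 1.15) with both, where DKK1 stood at -2.20 and TNFRSF19 at 3.07. The IGF and insulin pathway list gave -0.28, -0.59 and -0.61 for the inhibitor arrays, with IGFBP3 at -4.36 with both. HOX genes gave -0.08, -0.12 and -0.90 for LY294002, insulin and both. FOXO targets gave 0.18 with IWP2 and 0.00 with both. Cholesterol synthesis gave -0.40 with IWP2 and -0.69 with both, the amino acid and stress list -0.50, 0.18 and -0.97 for IWP2, insulin and both, and the glycolysis list 0.20, -0.12 and -0.05 for the inhibitor arrays. Cardiac transcription factors gave 0.28 with LY294002 and -0.08 with insulin, and oxidative metabolism -0.05 with insulin. Reference genes of general use gave -0.06, -0.08, -0.10 and -0.18, though TUBB stood at -2.51 with both inhibitors.

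Comparisons between treated arrays do not use the control. Between both inhibitors and IWP2 alone, 243 genes detected on both arrays were at least 2-fold higher and 283 lower, and the lower side was led by DLK1 (-5.57) and then by liver genes: TTR differed by -5.43, SERPINA1 by -4.76, FGB by -4.14 and APOA2 by -3.85. Its counts were less even without background correction (47 higher and 104 lower) and at 3-fold (20 and 78). The endoderm and liver list median of that comparison was -3.78 (percentile 0) and the cardiomyocyte list median 0.21 (percentile 98.8). PNPLA8 (2.37), SPDL1 (2.22), CHURC1 (2.11), SELENOT (1.99) and ALX1 (1.97) led the higher side. Between both inhibitors and LY294002 alone, 455 of 7691 genes were higher and 336 lower. KIF1B (2.94), LMO3 (2.84), A2M (2.53), ERH (2.43) and RWDD4 (2.26) were higher, NHERF1 (-4.20), MSX1 (-3.86), HOXB5 (-3.63), SBSPON (-3.28) and H19 (-3.04) lower, and SLN was at least 17.1-fold lower. Between LY294002 and IWP2, 329 of 7980 genes were higher and 446 lower. The cardiomyocyte list median there was 0.07 (percentile 81.2) and the endoderm and liver median -2.26 (percentile 0), with AHSG at -3.17 and APOC3 at -3.10. GSTA1 (-3.65), A2M (-3.51) and TGFBI (-2.88) were also lower, and CENPK (2.63), GAP43 (2.52), SPDL1 (2.38), H2AC18 (2.08) and TMEM216 (2.06) higher.

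Insulin and LY294002 act on PI3K in opposite ways, and 981 of 7736 genes were at least 2-fold higher and 923 lower on the insulin array than on the LY294002 array (24.6%). APOC3 (6.40), GSTA1 (5.95), AHSG (5.54), FGA (5.19) and APOA4 (4.97) were higher with insulin. MB (-5.03), CKM (-4.99), PLN (-4.59), SMPX (-4.39) and HSPB7 (-4.15) were lower, and IRX4 was at least 28.0-fold lower. The endoderm and liver median was 4.05 (percentile 100) and the cardiomyocyte median -2.17 (percentile 0). Most of both gaps lay on the LY294002 side. Against the control, the endoderm and liver median was 0.14 with insulin and -3.68 with LY294002. The cardiomyocyte medians were -0.51 and 1.64. APOC3, AHSG and APOA4 were not higher with insulin than in the control (-0.26, -0.25 and -0.13).

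The labels form a 2 by 2 layout of IWP2 and LY294002, and the 2 by 2 difference is the IWP2 difference on LY294002 minus the IWP2 difference without it. Of the 5 genes that led its negative side, MB (-4.85), IRX4 (-3.94), NKX2-5 (-3.90) and CKMT2 (-3.76) were cardiac list members and WNT2 (-3.81) was a WNT ligand. All 20 cardiomyocyte genes detected on the 4 arrays had a negative value, 17 of them past 2-fold (median -1.62). Their single-inhibitor differences summed to a median of 4.06, and the double-inhibitor difference had a median of 2.11. The 9 endoderm and liver genes detected on the 4 arrays had a median of -0.08. That median is the value of GATA4, which stayed near the control with IWP2 (0.005), LY294002 (-0.10) and both inhibitors (-0.17). The other genes lay on both sides of it, with TTR negative and FGA positive. The 12 list members not detected with both inhibitors are left out. The median therefore does not show that the liver differences add. The positive side was led by ERH (3.49), LIME1 (3.17), TGFBR3 (3.10), TM4SF1 (3.07) and LHX2 (3.04). Of 7271 genes, 606 were past 2-fold on the positive and 700 on the negative side.

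Across the 7110 genes detected on all arrays, the IWP2 difference without LY294002 correlated with that on LY294002 (Pearson r = 0.341, Spearman rho = 0.316). Of 192 genes past 2-fold in both, 173 had the same sign, where independent lists would give 51.4. The LY294002 difference without IWP2 correlated with that on IWP2 (r = 0.422, rho = 0.371), with 178 of 188 genes of the same sign. The insulin difference ran against the LY294002 difference on IWP2 (r = -0.144, rho = -0.142), with 24 of 27 genes of opposite sign where independent lists would give 7.996. Without a detection filter this Pearson r was -0.0923. Opposite signs were not particular to LY294002. Against the IWP2 difference on LY294002, a pair chosen after seeing the data, 36 of 45 genes were opposite where independent lists would give 13.0. Genes are not independent replicates, so these values describe the arrays.

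**Figure D3:**
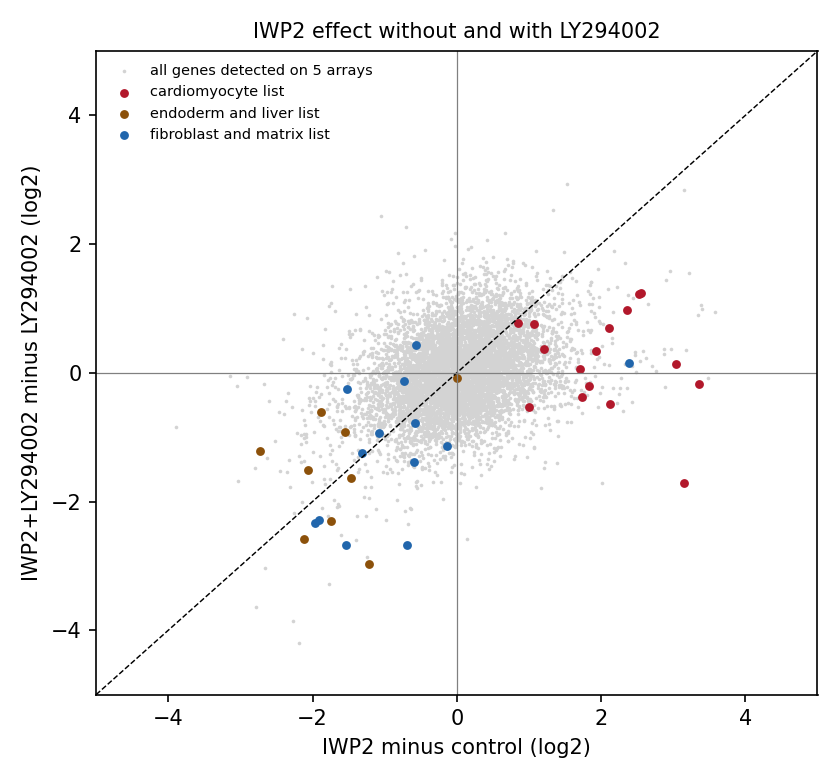
Log2 difference of IWP2 from control (horizontal axis) against that of both inhibitors from LY294002 alone (vertical axis) for 7104 genes detected on all 5 arrays, Y-linked genes left out; coloured points are list members and the dashed line marks equal differences. Of the cardiomyocyte list 16 genes are drawn, to the right of 0 and below the dashed line.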

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

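The tests of normalization, of a loss of liver-like cells, of the share of adult hepatocyte genes detected, of carry-over and of the sign of the cardiomyocyte genes were chosen after the result was seen, and the tests of adult liver levels, signal saturation and second probes over all genes were chosen before.

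Cardiomyocyte genes were higher and liver genes lower on the 3 inhibitor arrays. Normalization as the whole cause was argued against by the lowest cardiomyocyte median over these arrays and all settings, 1.045 on the log2 scale. A loss of liver-like cells alone would raise the genes of all other cell types, and the highest of the 9 fibroblast, epicardium and endothelium medians was -0.6711, or -0.351 with undetected members at their bounds. A shift of the cultures toward cardiac cells with the inhibitors is a candidate explanation from the treatments, as is variation between cultures, which 1 array per group leaves open.

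Liver transcripts were among the brightest signals of the control array. RNA from adult liver was argued against by the detection of 10 of 28 adult hepatocyte genes (35.71%), with HPX (9.24), CPS1 (7.70), ORM1 (7.68) and ARG1 (6.44) detected and CYP3A4, CYP2E1, SAA1 and CRP not. The median of these genes lay 7.028 below that of the liver list on the log2 scale, which decides nothing, since signals of different probes do not rank transcript abundance. Carry-over onto 1 array was argued against by 3 arrays with a liver median at least 2 over their detection floor. Cells with a fetal liver or yolk sac program in the cultures may be the source, which the arrays cannot separate by cell.

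Cardiac genes with both inhibitors lay below the sum of the single differences. Signal saturation was weighed by the cardiomyocyte genes within 1 of the array's highest signal on the log2 scale. These were 3 of the 35 detected on any array (8.571%), under the bound set in advance. All 3 (MYH6, MYL4 and MYL7) are among the 20 genes that carry the pattern, and 3 of 20 is past that bound. Saturation therefore stayed open for these 3. ACTC1, at 13.37 against a highest signal of 14.48, lay only just outside that limit, so saturation stayed open for it too. The rest of the 20 lay further below the highest signal, which argues against saturation for them. Error of single probes stayed open over all genes: second probes had the same sign in 182 of 245 genes (74.29%), where over 75% had been set in advance as the bound against it. For the cardiomyocyte genes alone 20 of 20 values were below 0, which restates the pattern and decides nothing. An error of a whole array enters all these values, and a common ceiling of cardiac differentiation may account for them as well.

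Some genes stood out because the difference for an inhibitor had opposite signs with and without the other inhibitor, past 2-fold both times, and with 1 array per group none of these differences was tested. There were 19 such genes for IWP2 and 10 for LY294002, fewer than the 50.5 and 44.3 that independent lists would give. ERH had a 2 by 2 difference of 3.487 and TM4SF1 of 3.071. MB had one of -4.85 and WNT2 of -3.811.

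Of the probes without a gene symbol, which no comparison uses, 2138 were detected on both the control and the double-inhibitor arrays, and 288 of them differed by at least 2-fold (13.5%).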

How the results depend on the processing

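No paired analysis was possible because each group has 1 array and the labels give no pairing, so the replicate number only names a sample. The counts of genes depended on the background handling and the threshold. The directions of the named gene differences from the control past 2-fold did not, though differences of that size are unlikely to change sign. Smaller differences and the named genes of the other comparisons were not checked for reversal. The 16 counts of genes and the count for the 2 by 2 difference all stayed within 1.5 times under 75th percentile scaling, cyclic loess, the deposited log2 values, a detection limit of 0.05 and the mean over probes. The 8 counts that do not use the LY294002 array did so when normalized without it, an alternative chosen after seeing the data. The deposited log2 values nearly repeat the values used here (Pearson r over 0.9999 on each array). Agreement under them is therefore a weak check. The balance of the insulin counts turned with the scaling: 123 genes were higher and 202 lower under 75th percentile scaling, against 186 and 146 under cyclic loess. With both inhibitors, 75th percentile scaling gave 867 higher and 929 lower and cyclic loess 898 and 905, so the majority of higher genes was not kept. The cause was not tested. No scaling moved the median of all genes by over 0.1 on the log2 scale. Of 407 named gene differences from the control past 2-fold, the 3956 values under alternatives held 0 reversals and 611 moves, 607 of them toward 0. Of 39 list medians past 0.58 in size, 417 alternative values held 2 reversals and 30 moves, all toward 0. A move means over 0.58 on the log2 scale. Correlations of the IWP2 differences ran from 0.302 to 0.361, of the LY294002 differences from 0.400 to 0.453, and of insulin with LY294002 on IWP2 from -0.162 to -0.0923. The cardiomyocyte medians ran from 1.19 to 2.07 (IWP2), 1.05 to 1.65 (LY294002), -0.657 to -0.196 (insulin) and 1.28 to 2.15 (both inhibitors). Signal over background limits what dim genes can show, since background left in the signal shrinks every log2 difference.

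Counts are given as higher and lower for each comparison. Without background correction they were 240 and 308 (IWP2), 282 and 366 (LY294002), 39 and 31 (insulin), 417 and 462 (both inhibitors), 47 and 104 (both against IWP2), 108 and 99 (both against LY294002), 69 and 150 (LY294002 against IWP2), 508 and 416 (insulin against LY294002), and 504 genes past the threshold in the 2 by 2 difference. The cardiomyocyte medians were then 1.188 (IWP2), 1.045 (LY294002) and 1.279 (both inhibitors). With the saddle-point fit and an offset of 50 the counts were 323 and 403 (IWP2), 395 and 484 (LY294002), 56 and 47 (insulin), 565 and 574 (both inhibitors), 88 and 139 (both against IWP2), 173 and 144 (both against LY294002), 114 and 212 (LY294002 against IWP2), 658 and 545 (insulin against LY294002), and 708 genes past the threshold in the 2 by 2 difference. With negative controls and an offset of 50 they were 384 and 472 (IWP2), 468 and 563 (LY294002), 65 and 64 (insulin), 656 and 640 (both inhibitors), 116 and 163 (both against IWP2), 236 and 177 (both against LY294002), 150 and 265 (LY294002 against IWP2), 748 and 625 (insulin against LY294002), and 844 genes past the threshold in the 2 by 2 difference. A larger offset or remaining background shrinks differences by construction. Without a detection filter, which adds genes by construction, they were 827 and 945 (IWP2), 970 and 1385 (LY294002), 206 and 215 (insulin), 1318 and 1499 (both inhibitors), 334 and 513 (both against IWP2), 788 and 605 (both against LY294002), 487 and 769 (LY294002 against IWP2), 1701 and 1241 (insulin against LY294002), and 2446 genes past the threshold in the 2 by 2 difference. That setting gave a correlation of -0.09225 between the insulin difference and the LY294002 difference on IWP2, and the cause was not tested. The primitive streak median with both inhibitors reversed from 0.99 to -0.1475 at a detection limit of 0.05 and to -0.01068 without a filter, as these settings add dim members to the list. At 1.5-fold the counts were 1483 and 1543 (IWP2), 1671 and 1654 (LY294002), 815 and 803 (insulin), 1969 and 1676 (both inhibitors), 1030 and 1011 (both against IWP2), 1315 and 1150 (both against LY294002), 1209 and 1309 (LY294002 against IWP2), 1821 and 1921 (insulin against LY294002), and 3053 genes past the threshold in the 2 by 2 difference. At 3-fold they were 157 and 254 (IWP2), 184 and 261 (LY294002), 18 and 10 (insulin), 291 and 349 (both inhibitors), 20 and 78 (both against IWP2), 50 and 62 (both against LY294002), 36 and 79 (LY294002 against IWP2), 372 and 263 (insulin against LY294002), and 328 genes past the threshold in the 2 by 2 difference. The share of higher genes moved by over 10 points in some settings. Between both inhibitors and IWP2 it went from 46.2% to 31.1% without background correction and 20.4% at 3-fold. Between LY294002 and IWP2 it went from 42.5% to 31.5% and 31.3% in those settings. At 3-fold it was 64.3% for insulin and 44.6% between both inhibitors and LY294002. The cause was not tested.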

Other observations

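The test of imprinted genes was chosen after the result was seen. H19, DLK1 and CDKN1C, imprinted genes tied to fetal growth, were lower with both inhibitors: H19 read 12.94 in the control and 6.98 there, DLK1 read 12.58 and 5.77, and CDKN1C differed by -2.92. These genes were singled out after their values were seen. Whether imprinted genes move together stayed open. The median of 23 detected imprinted genes with both inhibitors was -0.40, at percentile 3 of matched random lists, just inside the bound of 2.5 set for the test. It was -0.11 (percentile 23.3) with IWP2 and -0.30 (percentile 9.45) with LY294002. With insulin it was 0.27 (percentile 99.3), outside the matching upper bound, with 3 of 20 genes higher and 0 lower. With both inhibitors, of 16 detected on both arrays, 3 were at least 2-fold lower and 1 higher. The list shares H19, IGF2 and IGF2R with the IGF and insulin pathway list and NNAT with the neural list.

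The insulin difference was also set against the IWP2 difference on LY294002, a pair chosen after seeing the data. Across genes the correlation was weak (Pearson r = -0.0707, Spearman rho = -0.0610). Of 45 genes past 2-fold in both, 36 had opposite signs, where independent lists would give 13.0.

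Where a gene past 2-fold had a second detected probe, that probe had the same sign in 212 of 255 genes with IWP2, 273 of 308 with LY294002 and 329 of 365 with both inhibitors. The second probe was itself past 2-fold in 95 (37.3%), 123 (39.9%) and 192 (52.6%) of those 255, 308 and 365 genes.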
